A study of Homo sapiens with 3 samples.

How the data were processed

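RNA of inflammatory cytokines, chemokines, growth factors and their receptors was measured by reverse transcription and quantitative PCR in normal human breast tissue. Per the labels' protocols, total RNA was used, product was followed with SYBR green over 40 cycles, and a melting curve was run for each reaction. The series holds 1 group of 3 samples, described as repeats. The tables name their columns A, B and C, and these letters cannot be tied to the repeat numbers, so the columns were used as 3 unnumbered replicates of the group. The labels used here do not say whether the repeats are separate tissue pieces, separate extracts or separate wells. The p-values therefore measure only the spread between these columns, which may be technical.

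The authors deposited a table of threshold cycles (Ct, the cycle at which fluorescence passes a threshold, so that a lower Ct means more template) and a table of levels as a linear percent of the ACTB level. Both list 179 rows, which are ACTB and 178 target genes. Cells marked ND in the deposited tables were read as not detected; how ND was called is not given in the sources used here, so no upper limit is attached to it. The deposited percent of ACTB was checked against the deposited Ct values. For every detected gene it equals 100 times 2 to the power of a reference Ct minus the gene's Ct, with a reference Ct that is the same in all 3 columns. That reference is 19.9 for ACTB and 74 targets and 21.55 for the other 49 targets. The first is the mean Ct of ACTB after rounding (19.87, 19.82 and 20.00 in columns A, B and C, mean 19.9). The second is not among the Ct values used here and its origin is not given in the sources used here. Of the genes in the fixed lists, all 61 detected ligands use the first reference and all 35 detected receptors use the second, and the remaining detected targets are split 13 and 14. Among these remaining targets, each one described as a receptor, such as NTRK2, PRLR and GHR, uses the second. Ligands among them, such as PRL, EDN1 and WNT1, use the first. The gap of 1.65 cycles corresponds to a factor of 3.14, by which every detected receptor is raised relative to the ligands compared with a single reference. Because the references do not vary between columns, the deposited values carry no correction for ACTB within a column. The formula was worked out from the values and is not stated in the files.

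Levels were averaged as log2 of the deposited percent of ACTB. They are printed as geometric means, with the SD in cycles (the SD of log2 level, n = 3 columns). The tables hold Ct readings and no counts of molecules, so the depth is unknown and no counting interval is given. Precision rests on the 3 readings per gene, and levels of different genes also differ by primer efficiency, which is not given in the sources used here. No batch or run date was given in the tables, and no column of sample values was left unused. The tables name no genome build, so no positions are printed. Gene names were compared with the RefSeq table of assembly GRCh38.p14, where 177 rows matched a current symbol and 2, CTGF and NOV, an older one. The names IL2R, IL3R and NOTCH were read as IL2RA, IL3RA and NOTCH1 from the deposited descriptions.

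A set of 32 gene lists, 133 ligand-receptor pairs, the tests and the rule for naming genes was fixed before the data were examined. The rule names the 10 highest and 10 lowest detected targets, the 5 genes with the largest SD, the highest and lowest member of each list with at least 3 detected members, both genes of the 8 largest pair differences past the threshold and of each VEGF, angiopoietin and CXCL12 pair, and every gene that was not detected. Beyond the rule, members of small counts, marker genes, pairs that did not pass or whose call ended under an alternative, and the genes discussed in the other observations were named after their values were seen. Ligand and receptor were compared within each column, as the log2 level of the ligand minus that of the receptor, with limma's one-sample moderated test and Benjamini-Hochberg adjustment over the 33 pairs detected on both sides (threshold 0.05, two-sided). With 3 columns an exact sign-flip test cannot go below a two-sided p of 0.25, which is why the spread was shared across pairs. The test was checked on simulated data with 200 panels of 33 pairs: it called 37.5% of true differences of 1 on the log2 scale, 69.9% of those of 2, 90.8% of those of 4 and 99.5% of those of 8. It called 4.21% of unchanged pairs, and 1.53% of its calls were false. The simulated true differences were 0, 1, 2, 4 and 8 in near-equal numbers, and the share of false calls holds for that mix. Simulated pairs were independent, while some real pairs share a gene. List medians were placed among 10000 random lists of the same size drawn from the detected targets, and the ligand-receptor difference among 10000 random assignments of genes, both as descriptions. Detection was compared between ligands and receptors with Fisher's exact test (two-sided).

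Results were recomputed with centring on the median Ct, levels taken from the Ct table with a single reference, 1.9-fold amplification per cycle, medians in place of means and the reverse, Ct limits, other ways of sharing the spread, limma's treat with a minimum difference of 1, and with each column left out. A Ct limit of 38, a single reference for the pairs, classes and lists, an unpaired fit, classes defined by reference Ct, and the removal of the 5 most variable genes were added after seeing the data. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and tests with R 4.3.3 and limma 3.58.1.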

Results

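The RNA of 178 target genes and of ACTB, which encodes beta-actin and served as the reference gene, was measured in 3 samples of normal breast tissue. The targets were chemokines, interleukins, members of the TNF and TGF-beta families, growth factors, hormones and the receptors of many of these. The series describes no second group here. The data therefore give which of these genes had a reading in these samples and at what level. They also give how the readings of ligands stand against those of their receptors. ACTB was read at a Ct of 19.9 ± 0.093 (SD, n = 3), and the median Ct of the detected targets was 27.9. Depth in molecules is unknown.

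Of the 178 targets, 123 were detected in all 3 columns and 55 in none, and no target was detected in only some of them. The levels reached from above that of ACTB to 0.000312% of it, with a median of 0.550%. At or above 10% of ACTB lay 26 genes, at or above 1% lay 56, and below 0.01% lay 21. A mean Ct of 35 or later was read for 17 genes.

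The highest level was that of CX3CL1, the membrane-anchored chemokine fractalkine, at 116% of ACTB ± 0.40 cycles (SD, n = 3, as for all levels that follow). CCL28, a chemokine of mucosal and glandular epithelia, followed at 79.4% ± 0.13. Among the 10 highest genes were 3 cytokines best known from T cells, with IL17A at 51.5% ± 0.023, IL5 at 45.7% ± 0.026 and IL2 at 42.8% ± 0.042. TGFB2, a growth factor of the TGF-beta family, stood at 38.6% ± 0.025. The other genes of the top 10 were receptors. CXCR4, the receptor of the chemokine CXCL12, stood at 51.9% ± 0.13, and NTRK2, the receptor of the neurotrophin BDNF, at 41.2% ± 0.046. KDR, the main VEGF receptor of endothelium, stood at 36.9% ± 0.98, and the chemokine receptor CCR5 at 34.3% ± 0.15. These 4 receptors were set against the later of 2 reference Ct values, and with the ACTB reference of the other genes their levels were 16.5%, 13.1%, 11.7% and 10.9%.

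The lowest detected gene was CXCL8, a neutrophil-attracting chemokine, at 0.000312% ± 1.93. The interferon-induced chemokine CXCL10 stood at 0.000765% ± 2.39, PRLR, the prolactin receptor, at 0.000810% ± 2.07, and the growth factor EGF at 0.000816% ± 1.09. CCL26 and CCL7, a pair of CC chemokines, stood at 0.00157% ± 0.36 and 0.00217% ± 0.81. The interleukins IL11 and IL17D stood at 0.00210% ± 1.47 and 0.00251% ± 0.37. PRL, the hormone prolactin, stood at 0.00315% ± 0.40 and TNFRSF17, a receptor of plasma cells, at 0.00329% ± 0.89. With SDs of up to 2.39 cycles, the order within these 10 genes is not resolved. PRLR and TNFRSF17 were set against the later reference Ct. With the ACTB reference they stood at 0.000258% and 0.00104%, which put PRLR below CXCL8 (0.000311%).

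**Figure D1:**
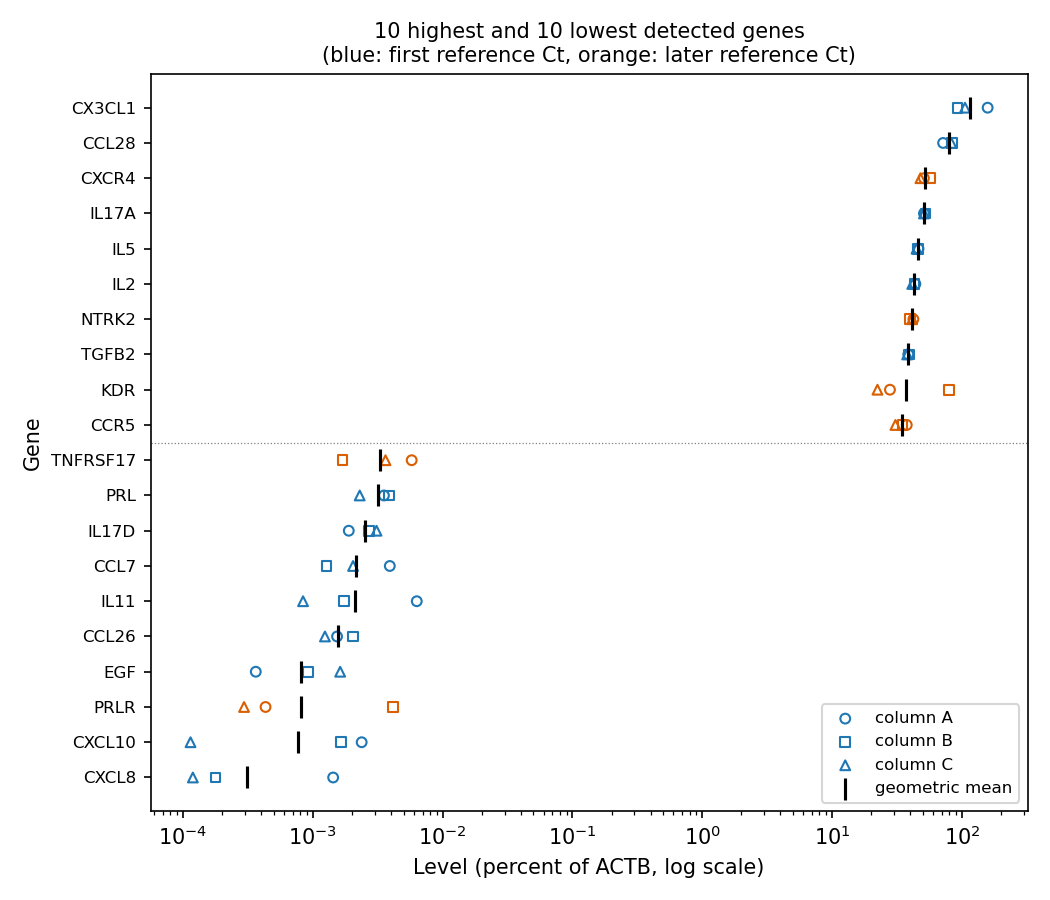
Level of the 10 highest and 10 lowest detected target genes as percent of ACTB on a log axis. Open symbols are the 3 columns, black bars the geometric means, and colour shows the reference Ct behind each gene (blue 19.9, orange 21.55). The upper genes lie between 34.3% and 116%, the lower ones at or below 0.00329%.

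Detection differed between the classes of the fixed lists. Of the ligands in the fixed lists 61 of 81 (75.3%) were detected, and of the receptors 35 of 63 (55.6%), an odds ratio of 2.44 (Fisher's exact test, p = 0.0200; genes are not independent replicates). The other 34 targets are in neither class of the fixed lists, although some are receptors (such as NTRK2 and PRLR) or ligands (such as PRL). The comparison was not run with them classed, so it holds for the listed genes only. The receptors were also the genes set against the later reference Ct.

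Undetected chemokines were CCL4, CCL5, CCL11, CCL13, CCL15, CCL20, CCL23, CCL24 and CXCL11, and undetected chemokine receptors were CCR4, CCR6, CXCR2 and CXCR6. Among interleukins, IL4, IL6, IL13, IL15, IL19, IL31 and IL33 were not detected. The interleukin receptors without a signal were IL1RL1, IL3RA, IL4R, IL5RA, IL6R, IL7R, IL11RA, IL13RA2, IL15RA, IL17RA, IL17RD and IL21R, as were CNTFR and LIFR of the IL-6 family. From the TNF families, TNFSF11, TNFSF12, TNFSF18, LTBR, TNFRSF13B, TNFRSF13C and TNFRSF18 were not detected. The remaining undetected targets were CSF1, CSF1R, CSF2RA, BDNF, FGFR2, IGF1R, FLT4, TGFBR1, ACVR2B, FSHB, FSHR, GH2, NOTCH1 and WNT3. Not detected means that no Ct was given in any column. The deposited annotation lists primers named for FGFR1 and WNT3A beside FGFR2 and WNT3.

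Interleukins outside the IL-1 and IL-6 families were the list with the highest percentile of its median. Of 15 on the panel 11 were detected, with a median of 11.4% of ACTB, and 6 of these lay in the highest 25% of detected targets. They ran from IL17A down to IL17D, and their median lay at percentile 99.2 of random lists. Of their receptors 5 of 13 were detected, with a median of 0.0420% (percentile 18.8; 0.0735% and percentile 3.71 over genes under Ct 35), from IL20RA, a receptor chain for IL-20, at 21.6% ± 0.064 to IL9R at 0.0109% ± 0.44. The difference between these 2 lists was not tested. In the fixed list of IL-6 family ligands, 3 of 4 were detected with a median of 0.0294% (percentile 20.2). LIF was the highest of them at 0.0391% ± 0.42 and IL11 the lowest. Of the family's 5 listed receptors on the panel, OSMR alone was detected. The lists leave out CLCF1 (2.46% ± 1.10) and IL31RA (20.4% ± 0.13), which also belong to this family.

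Of 18 CC chemokines 10 were detected, with a median of 0.0376% (percentile 6.10), and 5 of these were in the lowest 25%, while CCL28 was the highest and CCL26 the lowest. This median was 0.0237% (percentile 2.27) without column A, 0.0596% (percentile 8.83) without column B and 0.550% (percentile 27.2) over genes under Ct 35. With the mean of the members in place of the median the percentile was 2.56. Of 7 CC chemokine receptors 5 were detected, with a median of 14.8% (percentile 95.0), and 4 were in the highest 25%. The difference between the 2 lists was not tested. CCR5 was the highest and CCR2, the receptor of monocyte chemoattractants, the lowest at 3.23% ± 0.20. The CXC, CX3C and XC chemokines had 13 of 14 members detected with a median of 0.405% (percentile 40.9), from CX3CL1 to CXCL8 (4.17% over genes under Ct 35). For their receptors it was 6 of 8 with a median of 0.109% (percentile 22.3), from CXCR4 to CX3CR1, the fractalkine receptor, at 0.00590% ± 1.75 (3.65% over genes under Ct 35). With a single reference Ct the medians of the receptor lists are lower by the factor of 3.14. The counts in the highest and lowest 25% rest on the 2 deposited references too.

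In the TNF receptor superfamily 5 of 9 genes were detected, with a median of 0.00881% (percentile 3.12) and 3 in the lowest 25%. TNFRSF12A, the receptor of TWEAK, was the highest at 5.39% ± 0.24 and TNFRSF17 the lowest. Without column B the median was 0.0142%. The TNF ligands had 5 of 8 detected with a median of 0.564% (percentile 51.7), from TNFSF13B, the B-cell survival factor BAFF, at 21.9% ± 0.025 to TNFSF14 at 0.0104% ± 0.13. Over the 17 lists with at least 3 detected members, 1 median lay outside the central 95% of random lists, where chance would place 0.85. That count was 1 or 2 in each alternative. The CC chemokine receptors ranged from percentile 86.1 to 99.4 over the alternatives, and the TNF receptors from 1.43 to 4.77, with too few members under Ct 35 to give a value there.

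All 3 VEGF ligands on the panel were detected, at a median of 0.0948% (percentile 26.3). VEGFC, which drives lymphatic growth, was the highest at 8.54% ± 0.55, and VEGFA, the main angiogenic factor, the lowest at 0.0228% ± 0.36. Of the VEGF receptors and neuropilins 3 of 4 were detected, with a median of 3.00% (percentile 69.4), from KDR to the co-receptor NRP2 at 0.0363% ± 1.43. FLT1, a second VEGF receptor, stood at 3.00% ± 0.062. The angiopoietins, which act on vessel stability, stood at 6.43% ± 0.017 for ANGPT2 and 5.28% ± 0.047 for ANGPT1. Their receptor TEK stood at 0.476% ± 1.11, and the median of the 3 genes was 5.28% (percentile 80.2). The blood endothelial markers on the panel were FLT1, KDR and TEK, with a median of 3.00% (percentile 69.4).

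Of the other growth factors 6 of 7 were detected with a median of 1.34% (percentile 68.0; 2.52% over genes under Ct 35), from HGF, a motility factor for epithelium, at 9.54% ± 0.22 to EGF. Of the other growth factor receptors in the fixed list 4 of 6 were detected, with a median of 1.19% (percentile 64.7). They ran from EGFR, the receptor of EGF, at 18.1% ± 0.099 to KIT at 0.0191% ± 0.76. NTRK2, at 41.2%, and FLT3, at 0.00703% ± 0.54, are not in that list. The 4 listed TGF-beta family ligands had a median of 3.00% (percentile 78.7). TGFB2 was the highest of them and TGFB1 the lowest at 0.0192% ± 0.63. Of the family's listed receptors 3 of 4 were detected, with a median of 0.242% (percentile 39.5). They ran from the signalling receptor TGFBR2 at 18.7% ± 0.083 to the co-receptor TGFBR3 at 0.224% ± 0.13. The lists leave out INHBB (1.40% ± 0.35), ACVR1B (0.00609% ± 0.58) and ACVR2B (not detected), which also belong to this family.

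The level of 12 lists moved by over 1.5 times when the mean log2 level of the members was taken in place of the median. It was then 2.29% for the interleukins outside the IL-1 and IL-6 families (percentile 96.7, below the CC chemokine receptors at 99.4) and 0.123% for their receptors. It was 0.0134% for the IL-6 family ligands, 0.0586% for the CC chemokines, 0.303% for the receptors of the CXC, CX3C and XC chemokines and 0.0320% for the TNF receptors. For VEGF ligands it was 0.264%, for VEGF receptors and neuropilins 1.59%, for angiopoietins with TEK 2.53%, for the other growth factors 0.504%, and for TGF-beta family ligands and receptors 1.61% and 1.00%.

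Lists with fewer than 3 detected members were described by detection alone. Colony stimulating factors had 2 of 3 genes detected and their receptors 0 of 3. IL-1 family ligands and receptors each had 1 of 2, and interferons and interferon receptors each 1 of 1. The leukocyte markers were represented by CSF1R, which was not detected. Of the lymphatic endothelial markers 1 of 2 was detected, CCL21, and of the fibroblast and pericyte markers 2 of 2, PDGFRA and CXCL12. Toll-like receptors, damage-associated ligands, adipokines, epithelial markers and adipocyte markers had no gene on the panel, so the cell makeup of the samples could not be read from them.

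Ligands were then compared with their receptors. The fixed pairs on the panel numbered 69, of which 33 had both genes detected, 20 the ligand alone, 9 the receptor alone and 7 neither. Of the 33, 29 differed past the threshold, 15 with the ligand higher and 14 with the receptor higher. Among pairs with the receptor higher, EGF lay below EGFR by a log2 difference of -14.44 ± 0.51 (SE, adjusted p = 6.75e-05). The chemokine CCL26 lay below CCR3, the receptor of eosinophils at 10.4% of ACTB, with a difference of -12.70 ± 0.39 (adjusted p = 6.75e-05). CXCL8 lay below CXCR1, which stood at 0.811%, with -11.34 ± 0.57 (adjusted p = 0.000106), and CCL7 lay below CCR2 with -10.54 ± 0.40 (adjusted p = 6.75e-05). TGFB1 lay below TGFBR2 with -9.93 ± 0.42 (adjusted p = 7.69e-05). Among pairs with the ligand higher, CX3CL1 lay above CX3CR1 with a log2 difference of 14.26 ± 0.88 (adjusted p = 0.000194), and IL2 above IL2RA, which stood at 0.0420%, with 9.99 ± 0.37 (adjusted p = 6.75e-05). The deposited annotation gives IL2 and the IL2 receptor the same primer name, so the identity of these readings is uncertain. Each of these 7 differences, and that of VEGFA against KDR, had the same sign in all 3 columns and lay past the threshold in every alternative that tested the pair. The limit of Ct 35 tested 3 of these 8 pairs (IL2 with IL2RA, TGFB1 with TGFBR2 and VEGFA with KDR), since the other 5 hold a gene read at or past it.

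For the vessel-related pairs, VEGFA lay below KDR by a log2 difference of -10.66 ± 0.41 (adjusted p = 6.75e-05) and below FLT1 by -7.04 ± 0.33 (adjusted p = 0.000106). VEGFC lay above NRP2 by 7.88 ± 0.75 (adjusted p = 0.000860) and below KDR by -2.11 ± 0.37 (adjusted p = 0.00620). The latter call ended with a single reference Ct, at -0.46 (adjusted p = 0.291). ANGPT1 and ANGPT2 lay above TEK by 3.47 ± 0.54 (adjusted p = 0.00414) and 3.75 ± 0.55 (adjusted p = 0.00376). CXCL12, a stromal chemokine at 4.17% ± 0.73 of ACTB, lay below CXCR4 by -3.64 ± 0.40 (adjusted p = 0.00142).

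The 4 pairs that did not pass were IL20 with IL20RA (-0.09, adjusted p = 0.788), TNFSF14 with TNFRSF14 (0.26, adjusted p = 0.788), OSM with OSMR (0.63, adjusted p = 0.263) and CCL2 with CCR2 (-2.17, adjusted p = 0.0686). With a single reference Ct, IL20 turned to lie above IL20RA (1.56, adjusted p = 0.00938) and OSM lay above OSMR (2.28, adjusted p = 0.00938). CCL2 with CCR2 passed with a mean-level trend in the spread (adjusted p = 0.0481) and without column C (-3.26, adjusted p = 0.00157). TNFSF14 with TNFRSF14 changed sign, with -0.175 without column A, -0.46 without column B and 1.415 without column C. For OSM with OSMR these values were 0.14, 0.865 and 0.885, and none of them passed for either pair. A gap of 2 cycles would have been called in 69.9% of simulated pairs, so these results do not show equal levels. A difference between a ligand and a receptor also holds the difference in primer efficiency and the 1.65-cycle gap between the references of the classes.

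**Figure D2:**
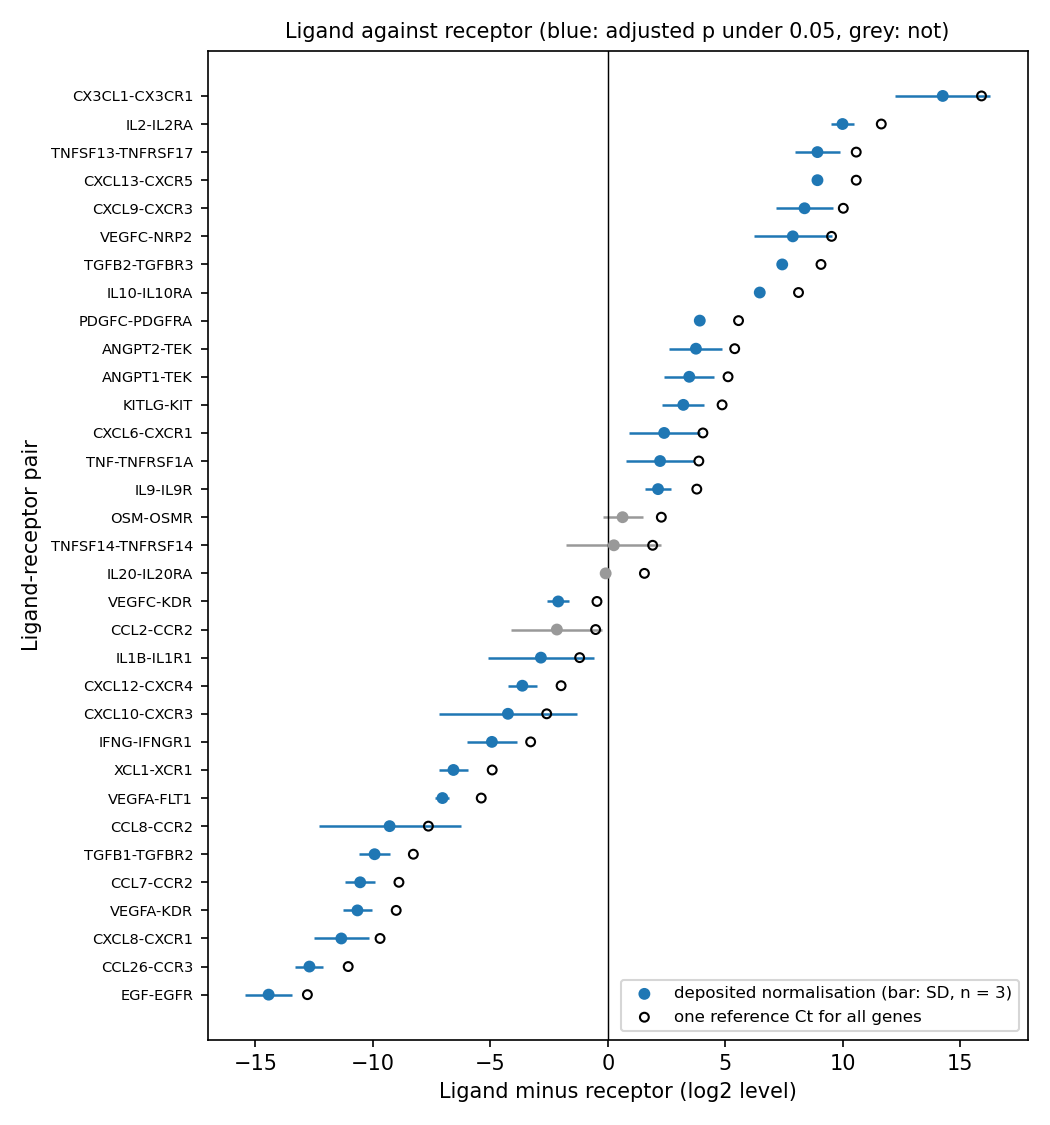
Ligand minus receptor in log2 level for the 33 pairs with both genes detected. Filled points and bars give the mean and SD over the 3 columns with the deposited references (blue past the threshold, grey not), and open points the value with a single reference Ct, which lies 1.65 higher throughout. The deposited values run from -14.44 for EGF with EGFR to 14.26 for CX3CL1 with CX3CR1.

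As classes, the ligands and receptors of the fixed lists did not differ beyond what random assignment gives. The 61 detected ligands had a median of 0.405% of ACTB and the 35 receptors one of 0.476%, and the difference of the medians was -0.26 ± 0.34 on the log2 scale (SD, n = 3), at percentile 44.5 of random assignments. With a single reference Ct the difference turned to 1.39 ± 0.34, at percentile 81.3. Classing all detected targets by reference Ct instead adds 13 targets outside the lists to the side of the ligands and 14 to that of the receptors. On the deposited levels the difference was then 1.67. That value was not placed among random assignments. The sign therefore depends on the reference and on which genes are classed.

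The 3 columns were close to each other in their overall level, with median deviations of -0.027, -0.013 and 0.047 cycles. Across the 123 detected genes, which are not independent replicates, Pearson's r between columns was 0.961 for A and B, 0.962 for A and C and 0.974 for B and C. The median SD of a gene was 0.33 cycles, 27 genes varied by less than 0.1 cycles and 19 by more than 1 cycle. The spread grew with Ct, from a median SD of 0.085 cycles at mean Ct 18 to 24 to 1.09 at mean Ct 35 to 40. The largest SD was that of MIF, a cytokine that restrains macrophage movement, at 4.69 cycles, with Ct values of 37.15, 29.69 and 28.5 in columns A, B and C. It was followed by the chemokine CCL8 with 3.15, the inflammatory cytokine IL1B with 2.75, CCL21, a chemokine of lymphatic vessels, with 2.56, and CXCL10 with 2.39. The mean levels of MIF (0.0265%), CCL8 (0.00517%), IL1B (0.295%) and CCL21 (0.0148%) are uncertain to that extent.

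**Figure D3:**
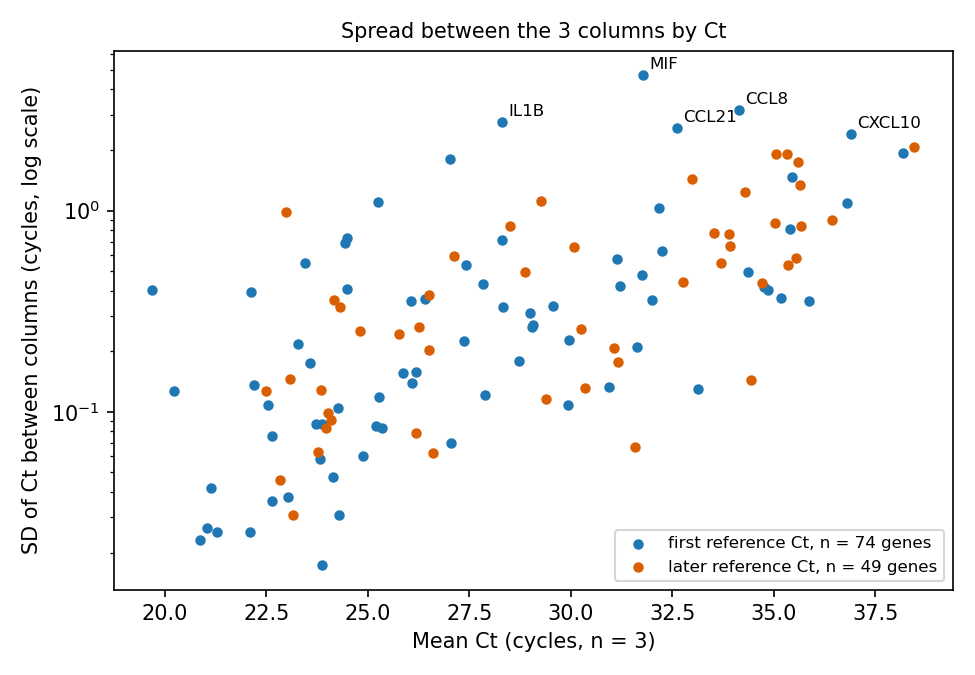
SD of Ct between the 3 columns on a log axis against the mean Ct, in cycles, for the 123 detected target genes (blue 74 genes with the first reference Ct, orange 49 with the later one). The 5 genes with the largest SD are named, with MIF at 4.69 cycles.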

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

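Tests with a single reference Ct for the pairs, classes and lists (for gene levels it was chosen before), an unpaired fit, classes by reference Ct, a Ct limit of 38 or without the 5 most variable genes were chosen after seeing the data. The count of detected genes (123, or 99 under Ct 35 and 120 under Ct 38) stayed within 1.5 times. Pairs past the threshold numbered 25 to 29 of 33 in the alternatives that kept every pair; with both genes under Ct 35 in every column they were 17, 7 of these with the receptor higher, because 21 pairs could be tested. With a single reference Ct 28 pairs passed, 17 with the ligand higher and 11 with the receptor higher. That setting lowers every receptor by construction. It turned the difference of the class medians to 1.39 and IL20 against IL20RA to 1.56 (adjusted p = 0.00938). IL20 with IL20RA passed in none of its 9 other alternatives. The single reference also brought OSM over OSMR past the threshold at 2.28 (adjusted p = 0.00938). On the deposited levels, with all detected targets classed by reference Ct, the class difference was 1.67. Its sign thus turned without the single reference too. Centred on the median Ct, and likewise with a single reference, 7 of the 10 highest genes stayed and 6 of the 10 lowest; NTRK2, KDR and CCR5 left the highest with a single reference, and genes at or above 10% of ACTB fell from 26 to 18.

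Calls of 6 pairs ended under an alternative, in each case without a change of direction. IL1B with IL1R1 (adjusted p = 0.0475) passed in 4 of its 10 alternatives. CXCL10 with CXCR3 ended without column A (adjusted p = 0.114), with a trend in the spread (0.0529), with its own spread (0.153) and with a single reference (0.114), and moved to -2.63 without column C. TNF with TNFRSF1A and CXCL6 with CXCR1 ended without column B (0.0663 and 0.0553), with their own spread (0.142 and 0.141) and with treat (0.0837 and 0.0737). IL9 with IL9R ended without column C (0.0551), where CCL2 with CCR2 passed (0.00157). VEGFC with KDR ended with a single reference. Leaving out each column, the mean correlation between columns was 0.961 to 0.974, and the class difference -0.42 to -0.08. With means in place of medians 5 lists lay beyond percentiles 5 and 95, against 3; the cause was not tested. The interleukin list stayed at percentiles 96.7 to 99.96. A 1.9-fold amplification rescales differences to 92.6% and cannot change the pair tests. Another reference gene was not run, as ACTB was the only one on the panel, nor a pseudocount, as no value was 0.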

Other observations

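The genes of this part were chosen after their values were seen, except those with the largest spread, and so were its tests, except the correlation across pairs. Several detected cytokines had a receptor chain on the panel without any signal. IL17A, IL5 and IL3, at 51.5%, 45.7% and 15.0% of ACTB, stood beside undetected IL17RA, IL5RA and IL3RA. LTB, near the panel's median at 0.564%, stood beside undetected LTBR. The reverse was seen for CCR5 at 34.3%, whose ligands CCL4 and CCL5 were not detected, and for NTRK2 at 41.2%, whose ligand BDNF was not detected.

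Among hormone-related genes, PRL was read at 0.00315% of ACTB and PRLR at 0.000810%, while GHR, the growth hormone receptor, stood at 0.271%, rank 70 of 123. PRLR and GHR were set against the later reference Ct, and with the ACTB reference they stood at 0.000258% and 0.0860%. The level of PRLR rests on Ct values of 39.37, 36.1 and 39.92 in columns A, B and C, near the last cycle. FSHB, FSHR and GH2 were not detected. PROK1 and PRKAR1A, at 16.2% and 4.01%, share a primer name in the deposited annotation, as IL2 and the IL2 receptor do, so the identity of these readings is uncertain.

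The cytokines IL2, IL3, IL5 and IL17A were read at 15.0% to 51.5% of ACTB, with SDs of 0.023 to 0.042 cycles. T cells in the tissue were weighed as the source through the detected T-cell genes that share the reference of these cytokines. Their median lay 2.71 cycles after the latest of the 4 cytokines, but the single gaps were 4.73 cycles for LTB, 2.71 for IL32 and -0.53 for IL16, which was read before it, so T cells stay open as a source. Of 10 T-cell genes listed, IL7R, CCL5, CCR4, CCR6 and CXCR6 were not detected and CXCR3 stood at 0.0146%, while CXCR4 stood at 51.9% and IL16 at 21.6%. Genomic DNA and unspecific products were not tested as a source, since no reaction without reverse transcriptase or template was used here, and stay open.

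In the fixed lists, receptors were read later and detected less often than ligands. Whether the whole receptor set was read later by the gap of the references cannot be told apart from chance for the later readings: on the 2 references the medians differed by -0.26 ± 0.34 (SD, n = 3), and the gap with a single reference lay at percentile 81.3 of random assignments. The origin of the later reference is not given in the sources used here. Whether the gap of the references accounts for the lower detection cannot be decided here. With every ligand reading moved 1.65 cycles later, 72.8% of ligands would still be read before cycle 40. Against this, 55.6% of receptors were detected (Fisher's exact test, p = 0.0354). That shift took the detected ligands only from 61 to 59, so it could change little. The test also takes cycle 40 as the limit of detection, while how ND was called is not given. No target was detected in only some columns, although readings came close to that cycle. Other reasons for ND calls, and a biological difference between the classes, were not tested.

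The 5 genes with the largest spread between columns had SDs of 15.2 (MIF), 8.58 (IL1B), 5.26 (CCL21), 5.18 (CCL8) and 2.80 (CXCL10) times the median SD of the 20 genes nearest in Ct. They were chosen for their spread, so these ratios decide nothing about few template molecules, which stay open. Unequal cDNA between the columns is argued against by the column medians, which lay within 0.073 cycles. Failed wells and separate tissue pieces stay open too, and no biological explanation was tested.

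The hypothesis that a ligand and its receptor are present at matched levels was tested across the 33 pairs. Spearman's rho was -0.194 (permutation p = 0.282) and Pearson's r -0.185 (permutation p = 0.303; -0.118 without the 2 pairs farthest from the median). The bootstrap interval of rho, -0.523 to 0.170, leaves out a strong positive relation. This is a correlation across genes, and the pairs share 31 ligands and 27 receptors, so they are not independent.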
